A study of Homo sapiens with 6 samples.

How the data were processed

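Poly(A)-enriched RNA of RBE cells was sequenced in 6 libraries, 3 labelled NC and 3 labelled sgKCNQ3, after random-primed reverse transcription and amplification on circularised DNA, per the labels' protocols. Whether the guide directed a nuclease or a repressor is not given in the sources used here. The deposited table held 16200 genes with Entrez IDs and symbols. The authors' estimated counts (expected counts) of reads per gene were deposited without normalization, and 5.52% to 6.33% of them per library were not whole numbers. The authors' TPM values, scaled to the same total over the genes of the table in each library, and their FPKM values stood beside the counts, per the file headers. The deposited table also held a signal column per library, the authors' read counts divided by 1 factor per library, and group means in TPM, FPKM, counts and as a whole-number score, none of which entered a test. The genome build was GRCh38.p13, per the submitters' processing notes. The aligner, the counter and their handling of strand and multiply mapped reads are not given in the sources used here.

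Libraries were assigned to groups and replicate numbers from their titles. Total counts ranged from 15601283 to 16089500, and the most abundant gene, EEF1A1, took 1.58% to 1.68% of them. The sum of the deposited FPKM values was 656809 to 668732 in NC and 630332 to 642515 in sgKCNQ3, a difference in the length makeup of the counted RNA. Within groups, counts of 2 libraries differed by 1.63 to 4.19 times the sampling variance (chi-square per degree of freedom), and between groups by 6.89 to 11.4 times, so no 2 libraries agreed within sampling noise. The first principal component of log2 CPM held 46.4% of the variance and separated the groups.

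Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at its defaults (minimum count 10), which left 12565 genes and removed 3635. Libraries were scaled with TMM factors, and the groups were compared with robust quasi-likelihood fits and F tests, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. The biological coefficient of variation was 3.62%. CPM is the count scaled to a fixed library total; CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. For any single gene an exact permutation test of 3 against 3 libraries could not go below 0.1, so the p-values rest on the model fitted across genes. Tested on simulated counts with the means and library sizes of this comparison (12505 genes, 50 changed genes per fold size), the procedure recovered 27, 40, 47 and 50 genes at log2 folds of 0.25, 0.5, 1 and 2. In that simulation 14 of 178 calls (7.87%) were false.

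Before the data were examined, 38 gene lists were fixed for the study's questions, the cell type, other cell types, stress, metabolism and library composition, and 37 held tested genes. Lists were compared with all other genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Fry, which asks whether a list moves on balance in a direction without comparing it with other genes, was run beside it. Named genes followed a rule fixed at the same time. It took KCNQ3, MAPK3, the 10 largest rises and 10 largest falls among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between groups, the 5 smallest p-values in each direction, and up to 4 called members per list with the smallest p. Some genes that the rule takes are not reported here. Genes named outside the rule are marked in the text as picked after their values were seen.

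Alternatives fixed beforehand were RLE, upper quartile and library-size scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), no filter, a filter of at least 2 CPM in 3 libraries, the replicate number as a block, and each library left out in turn. After the FPKM sums had been seen, a test with each library's trend over transcript length and GC content removed (natural splines with 5 degrees of freedom) was added. Length and GC came from the longest protein-coding transcript in GENCODE release 29, matched by Entrez ID or symbol for 16032 genes. Gene types came from a RefSeq table matched for 16163 IDs. Figures were drawn with matplotlib 3.10.9.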

Results

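RNA abundance was measured by poly(A)-enriched RNA sequencing in RBE cells, an established human intrahepatic cholangiocarcinoma (bile duct cancer) line. The data comprised 6 libraries in 2 groups of 3. One group is labelled NC and served as the reference, and the other is labelled sgKCNQ3, the usual short form for a single guide RNA directed at KCNQ3. KCNQ3 encodes a voltage-gated potassium channel subunit best known from neurons. Total estimated counts were 15601283, 16089500 and 15825380 in NC replicates 1 to 3, and 15693876, 15722455 and 15685137 in sgKCNQ3 replicates 1 to 3. The depositors' question was which downstream genes respond to KCNQ3 loss in these cells, with ERK1/2 signalling, proliferation, apoptosis, invasion and epithelial-mesenchymal transition named as points of interest. The labels do not state that libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

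KCNQ3 mRNA was modestly lower in the sgKCNQ3 libraries. KCNQ3 (Entrez gene ID 3786) lies on the minus strand of chromosome 8, from 132120858 to 132481019 in GRCh38 (GENCODE release 29). The position of the guide within the gene is not given in the sources used here. NC libraries held 256, 257 and 252 KCNQ3 counts, and sgKCNQ3 libraries held 222, 206 and 191. In library-scaled counts (CPM) this was 16.3 ± 0.254 in NC and 12.99 ± 1.0 in sgKCNQ3 (SD, n = 3 each), so every sgKCNQ3 library lay below every NC library. The log2 fold change of KCNQ3 was -0.33 (SE 0.0841), with an edgeR quasi-likelihood adjusted p of 0.00446, so that its mRNA fell by 20.4%. A guide that disrupts the protein need not lower the mRNA, and protein was not analysed here. On log2(TPM + 1), the difference for KCNQ3 was -0.15 (limma adjusted p 0.140), past no threshold. That scale shrinks the change of weakly expressed genes. It also moved the median log2 fold change over the tested genes from -0.007 to 0.065. With each library's length and GC trends removed, its log2 fold change was larger in size, at -0.46 (edgeR adjusted p 1.69e-04). Of the other subunits of the KCNQ and KCNE list, KCNQ1 rose (log2 fold change 0.46, SE 0.159, adjusted p 0.0306). In all, 2 of its 4 tested members were called, and 4 adjusted over the list alone, and the list as a whole was not called (camera adjusted p 0.340).

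Many genes differed between the groups, nearly always by a small amount. Of 12565 genes tested, 3658 (29.1%) were called at the adjusted threshold, 1763 higher and 1895 lower in sgKCNQ3. The median absolute log2 fold change of called genes was 0.23, and 3286 of them (89.8%) changed by less than 0.5. A log2 fold change of at least 1 in size was reached by 59 called genes, 31 higher and 28 lower. Among called genes 94.9% had groups that did not overlap, against 41.7% of tested genes and 10% by chance for 3 against 3. The share of higher genes among the calls was 48.2% with TMM factors and 64.5% with library size alone. It was 81% with limma-trend on log2(TPM + 1), which changes the test and the unit as well, and 39.7% (1321 higher, 2005 lower) with length and GC trends removed. DESeq2 called 2322 genes. Fold change also rose with transcript length across genes (Spearman's rho 0.32) and fell with GC content (rho -0.26), genes not being independent replicates. The rho of each library's deviation with length was -0.174, -0.329 and -0.238 in NC and 0.275, 0.210 and 0.248 in sgKCNQ3.

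The largest rises were ranked among genes with a mean log2 CPM of at least 2. TNS4, a focal adhesion protein of the tensin family, rose from 8.46 ± 0.300 to 21.5 ± 0.796 CPM (log2 fold change 1.35, SE 0.0849, adjusted p 2.28e-11). PROX1, a transcription factor of liver progenitors, rose by 1.12 on the log2 scale (adjusted p 1.28e-05), and ERBB3, a receptor of the EGF receptor family, by 1.06 (adjusted p 2.36e-07). FRK, a non-receptor tyrosine kinase, rose by 0.98. A1CF, a cofactor of APOB mRNA editing, rose by 0.93, and ALDH1A1, a retinaldehyde dehydrogenase, by 0.92. ZNF704 (0.90), SESN3 (0.87), SATB1 (0.84) and RAB27B (0.84) completed the set of 10. The smallest p-values among higher genes belonged to LGR4, a receptor for R-spondins (0.73), TNS4, the surface glycoprotein CD24 (0.68), the epithelial transcription factor ELF3 (0.65) and HSPA1B (0.79).

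The largest falls were ranked in the same way. KRTAP2-3, a keratin-associated protein gene, fell from 14.8 ± 1.11 to 3.88 ± 0.335 CPM (log2 fold change -1.93, SE 0.113, adjusted p 9.16e-12). FST, which encodes the activin antagonist follistatin, had a log2 fold change of -1.23, and the scavenger receptor gene CD163L1 -1.05. HMOX1, the heme-degrading enzyme heme oxygenase, fell from 54.4 ± 1.37 to 27.0 ± 3.46 CPM (log2 fold change -1.01). OASL (-0.91) and the Wnt antagonist DKK1 (-0.86) fell as well. The smallest p-values among lower genes belonged to DUSP5 (-0.70), KRTAP2-3, the phospholipase gene PLCB4 (-0.64), and the stanniocalcin genes STC1 (-0.58) and STC2 (-0.61).

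Reads of several of these genes can be shared with near-identical or overlapping genes, which can leave the values of a single gene uncertain. EIF3CL had the largest fall (log2 fold change -3.84, SE 0.881, adjusted p 0.0403), but its summed counts with the paralog EIF3C were 8991, 9429 and 9248 in NC and 8792, 9180 and 8631 in sgKCNQ3. EIF3CL also lost its call without a filter, with the replicate block and in 5 of the 6 tests that left out a library. COMMD3-BMI1 (-0.80) is a readthrough locus that overlaps COMMD3 and BMI1. The summed counts of these genes were 4748, 4694 and 4818 in NC against 4147, 4186 and 4109 in sgKCNQ3. A shift of reads among them therefore cannot be the whole fall. HSPA1B and HSPA1A are near-identical, and their sum was 887, 990 and 996 counts in NC against 1629, 1700 and 1637 in sgKCNQ3. The rise of the pair therefore does not depend on how reads were split between them.

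**Figure D1:**
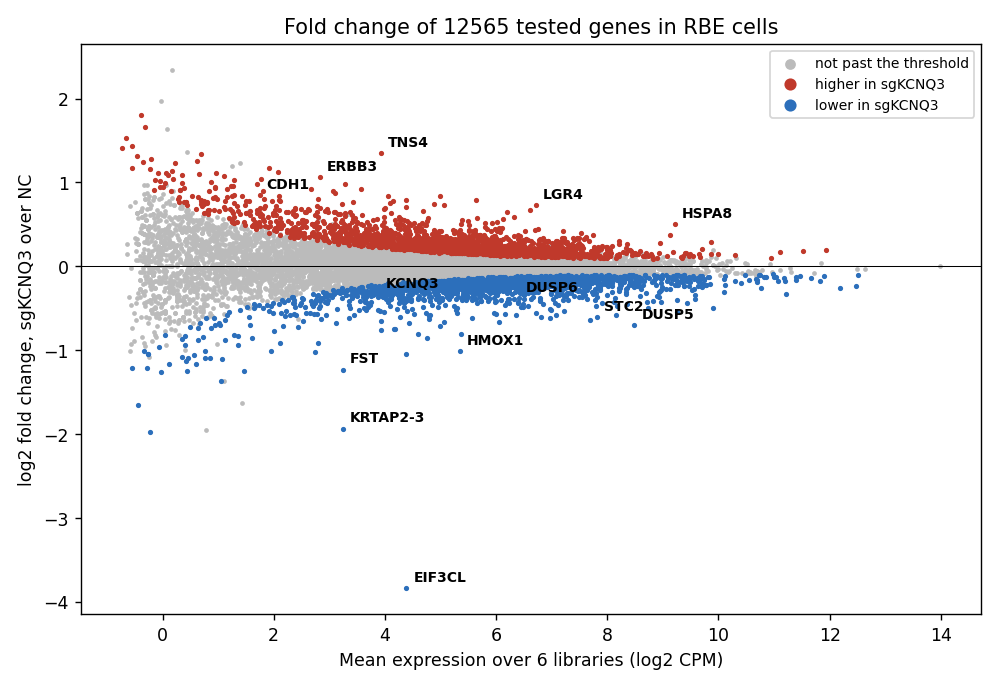
Log2 fold change of sgKCNQ3 over NC (vertical axis) against mean log2 CPM over the 6 libraries (horizontal axis) for 12565 tested genes. Red points are the 1763 genes called higher and blue points the 1895 called lower, grey points passed no threshold, and most called genes lie close to 0.

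Genes that report ERK1/2 output moved in both directions. Of 20 tested targets of the ERK1/2 pathway, 5 were called higher and 10 lower (17 called adjusted over the list alone). DUSP5, a nuclear ERK phosphatase, fell from 445 ± 12.8 to 273 ± 8.61 CPM. PHLDA1 (-0.35), the AP-1 subunit gene FOSL1 (-0.36), EPHA2 (-0.35) and DUSP6, a cytoplasmic ERK phosphatase (-0.38), fell as well. The other genes called lower were IER3 (-0.34), PHLDA2 (-0.39), SPRY4 (-0.24), SPRY2 (-0.18) and ETV5 (-0.19). DUSP4 (0.34), ETV1 (0.56), the signalling inhibitors SPRED1 (0.31) and SPRY1 (0.65), and CCND1 (0.14) were those called higher. SPRY1 lay at 3.62 CPM in NC, against 153 for SPRY2 and 81 for SPRY4. DUSP6, IER3, PHLDA2, SPRY4, SPRY2, ETV5, DUSP4, ETV1, SPRED1 and SPRY1 were picked from the list after their values were seen. The list had a median log2 fold change of -0.18 and was not called (camera adjusted p 0.119, and adjusted p = 0.380 with an estimated correlation). It was called with limma-voom (adjusted p 0.0231), on TPM (0.0330) and by fry (0.00510), within a range of 0.00510 to 0.510 over the alternatives. MAPK3, which encodes ERK1, passed no threshold (log2 fold change -0.09, adjusted p 0.319).

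Among 32 components of the RAS-RAF-MEK-ERK cascade, 12 were called higher and 3 lower (16 called adjusted over the list alone). ERBB3, the RAS GTPase-activating protein gene NF1 (0.34) and the kinase gene RPS6KA3 (0.30) rose, and PEA15 (-0.27), which encodes an ERK-binding protein, fell. The list was not called (camera adjusted p 0.0850). It was called with limma-voom (0.0471), on TPM (0.0330) and by fry (0.00351).

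Immediate early genes, the first genes transcribed after a growth or stress stimulus, were mostly lower. Of 24 tested, 14 were called lower and 1 higher (16 called adjusted over the list alone), with ATF3 at -0.47, CCN1 at -0.40, KLF2 at -0.62 and DUSP1 at -0.31. As a list they were called lower (median log2 fold change -0.18, camera adjusted p 0.00122, adjusted p = 0.214 with an estimated correlation). Its call ended when the length and GC trends were removed (median -0.15, adjusted p 0.323).

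The list of mitotic genes was called lower by a small amount, and that of DNA replication genes was not called. Of 33 G2/M and mitosis genes, 21 were called lower and 1 higher (24 called adjusted over the list alone). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell from 149 ± 5.98 to 104 ± 7.17 CPM (log2 fold change -0.52), the phosphatase gene CDC25B by 0.32 on the log2 scale, and the mitotic kinase genes PLK1 and CDK1 had log2 fold changes of -0.34 and -0.28. As a group, G2/M genes were called lower (median -0.18, camera adjusted p 4.13e-06, adjusted p = 0.199 with an estimated correlation). Of 34 S phase and DNA replication genes, 4 were called higher, including MCM3 (0.32), and 7 lower, including RRM2 (-0.31), with 11 adjusted over the list alone, and the list was not called (camera adjusted p 0.545). Of 11 cell cycle inhibitors, 3 were called higher and 5 lower (9 called adjusted over the list alone), with GADD45A at -0.62, BTG1 at -0.31, GADD45B at -0.38 and CDKN1A at -0.23, and that list was not called either (camera adjusted p 0.383).

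Apoptosis genes changed in both directions. Of 28 pro-apoptotic genes, 6 were called higher and 9 lower (16 called adjusted over the list alone). The BH3-only gene BCL2L11 (0.44) and the death ligand gene TNFSF10 (1.03) rose, and PMAIP1 (-0.24) and the death receptor gene TNFRSF10B (-0.18) fell. TNFSF10 was weakly expressed, at 1.51 CPM in NC and 3.11 CPM in sgKCNQ3. The median of this list was -0.09 and its mean 0.04, and it was not called (camera adjusted p 0.466, direction lower). Of 10 anti-apoptotic genes, 3 were called higher and 6 lower (9 called adjusted over the list alone), with BCL2L1 at -0.26, BIRC2 at -0.29, BIRC3 at -0.32 and XIAP at 0.25. That list was not called (camera adjusted p 0.154), but was called on TPM (0.0457), by fry (0.00256) and with the length and GC trends removed (0.0110, adjusted p = 0.286 with an estimated correlation). Of 24 p53 target genes, 12 were called lower and 3 higher (17 called adjusted over the list alone), with SESN2 at -0.41, GDF15 at -0.42, CDKN1A at -0.23 and TP53INP1 at 0.46. The p53 list was called lower (median -0.13, camera adjusted p 0.0175, adjusted p = 0.214 with an estimated correlation), and not with the length and GC trends removed (median -0.07, adjusted p 0.323).

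The epithelial junction list was called higher, while called mesenchymal genes went both ways. Of 23 epithelial junction genes, 9 were called higher and 1 lower (10 called adjusted over the list alone). The desmosomal genes DSP (0.43), DSG2 (0.35) and DSC2 (0.61) rose, and the tight junction gene CLDN1 fell (-0.31). CDH1, which encodes E-cadherin and was picked from this list after its value was seen, rose from 2.30 ± 0.225 to 4.15 ± 0.418 CPM (log2 fold change 0.85). The list was called higher (median 0.21, camera adjusted p 0.0102, adjusted p = 0.237 with an estimated correlation), but not without sgKCNQ3 replicate 3 (median 0.15, adjusted p 0.0873). Of 20 mesenchymal genes, 5 were called higher, including COL5A1 (0.23) and TNC (0.17), and 4 lower, including the integrin gene ITGA5 (-0.40) and ACTA2 (-0.21), with 9 adjusted over the list alone. That list was not called by camera (adjusted p 0.313), and was called higher by fry (0.0386). Of 25 invasion proteases and adhesion receptors, 8 were called higher and 6 lower (14 adjusted over the list alone), with the urokinase system genes PLAU (-0.31) and PLAUR (-0.45) lower and ADAM10 (0.31) higher, and the list was not called (camera adjusted p 0.484).

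Biliary and hepatocyte marker lists were called higher, with about as many members past no threshold as called. Of 14 cholangiocyte and cholangiocarcinoma markers, 7 were called, each higher (7 adjusted over the list alone): CD24 rose from 74.8 ± 2.40 to 120 ± 3.38 CPM, and KRT8 (0.28) and ANXA4 (0.24) rose less. The list was called higher (median 0.17, camera adjusted p 0.00152, adjusted p = 0.214 with an estimated correlation). Of 24 hepatocyte markers listed, only 8 passed the filter. Of these 8, 4 were called, each higher (5 adjusted over the list alone), at 2.20 to 4.73 CPM in NC. They were APOH (0.49) and the fibrinogen genes FGA (0.65), FGB (0.46) and FGG (0.34), which all lie on chromosome 4 and may not be separate changes. That list was called higher too (median 0.28, camera adjusted p 0.00441, adjusted p = 0.214 with an estimated correlation). FGG lost its call in each of the 6 tests that left out a library, in DESeq2, in limma-voom, without a filter and with the replicate block. Of 6 fibroblast, endothelial and leukocyte markers, PDGFRA (0.59) was higher and CD68 (-0.27) and CSF1R (-1.21) lower, with 3 adjusted over the list alone. CSF1R lay below 1 CPM in both group means, and the list was not called (camera adjusted p 0.816).

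The integrated stress response list was called lower and the heat shock list higher. Of 23 integrated stress response genes, which respond to amino acid shortage and misfolded protein, 17 were called lower and 2 higher (19 adjusted over the list alone). STC2 fell from 272 ± 4.67 to 179 ± 7.01 CPM, PPP1R15A had a log2 fold change of -0.50, ATF3 -0.47 and SESN2 -0.41. The list was called lower (median -0.21, camera adjusted p 4.13e-06, adjusted p = 0.199 with an estimated correlation). Of 14 heat shock genes, 8 were called higher and 1 lower (9 adjusted over the list alone), with HSPA8 rising from 491 ± 2.88 to 696 ± 33.1 CPM, and HSPA1A (0.73) and DNAJA1 (0.34) higher. HSPA1A and the near-identical HSPA1B are counted as 2 of these genes and may not be separate changes. The heat shock list was called higher (median 0.15, camera adjusted p 0.0114, adjusted p = 0.380 with an estimated correlation). Of 22 NRF2 targets, 10 were called lower, with SRXN1 at -0.47 and OSGIN1 at -0.66 beside HMOX1, and 4 higher, including ABCC2 (0.30), with 16 adjusted over the list alone, and that list was not called by camera (adjusted p 0.0850). It was called lower with limma-voom (0.0226) and by fry (0.00205). Of 19 unfolded protein response chaperones, 5 were called lower, including HSPA5 (-0.33), HERPUD1 (-0.30) and XBP1 (-0.23), and 3 higher, including SEL1L (0.34), with 11 adjusted over the list alone (camera adjusted p 0.408). Of 24 hypoxia targets, 6 were higher, including CA12 (0.77) and EGLN3 (0.56), and 7 lower, including ANGPTL4 (-0.34), with 13 adjusted over the list alone. The hypoxia list had a median of -0.01 and a mean of 0.04 and was not called (camera adjusted p 0.816, direction lower).

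NF-kB target and cytokine lists were called lower, while interferon-stimulated and antigen presentation lists were not called. Of 19 NF-kB targets, 10 were called lower and 2 higher (13 adjusted over the list alone), with TRAF1 at -0.61, RELB at -0.59, NFKB2 at -0.36 and the chemokine gene CXCL8 at -0.66. NF-kB targets as a list were called lower (median -0.28, camera adjusted p 0.00173, adjusted p = 0.199 with an estimated correlation). Of 18 cytokines and chemokines, 7 were called lower and 2 higher (9 adjusted over the list alone): IL11 fell from 80.7 ± 2.51 to 51.1 ± 1.34 CPM and LIF from 148 ± 2.86 to 104 ± 0.933 CPM, while CX3CL1 rose (0.44). That list was called lower (median -0.21, camera adjusted p 0.0142, adjusted p = 0.214 with an estimated correlation). Its call ended without a filter (median -0.12, adjusted p 0.126) and with the length and GC trends removed (median -0.22, adjusted p 0.154). Of 28 interferon-stimulated genes, 7 were called lower, including OASL, ISG20 (-0.47), ISG15 (-0.58) and IFIT1 (-0.59), and 1 higher, with 8 adjusted over the list alone (camera adjusted p 0.229). Of 19 antigen presentation genes, 2 were called lower, including HLA-B (-0.23), and CANX (0.14) was higher, with 3 adjusted over the list alone (camera adjusted p 0.475).

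Ribosomal protein and glycolysis lists were called slightly lower. Of 45 ribosomal protein genes, 17 were called, each lower (17 adjusted over the list alone), with RPSA at -0.26, RPL13 at -0.20, RPS9 at -0.19 and RPL13A at -0.18. The list was called lower (median -0.07, camera adjusted p 0.00173, adjusted p = 0.380 with an estimated correlation). Of 19 glycolysis genes, 9 were called, each lower (9 adjusted over the list alone), with the glucose transporter gene SLC2A1 at -0.24, SLC16A3 at -0.22, ALDOA at -0.15 and TPI1 at -0.14. The glycolysis list was called lower (median -0.09, camera adjusted p 0.0192, adjusted p = 0.380 with an estimated correlation). The ribosomal call ended without sgKCNQ3 replicate 3 (0.0516), by fry (0.0627) and with the length and GC trends removed (median -0.049, adjusted p 0.709), where its direction by camera turned. The glycolysis call ended without sgKCNQ3 replicate 1 (0.0764) or 3 (0.0541), on TPM (0.149) and with the trends removed (median -0.027, adjusted p 0.915).

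The remaining lists fixed before the data were examined were not called by camera with TMM-scaled counts of all 6 libraries. Of 34 nuclear-encoded oxidative phosphorylation genes, 5 were called, each lower (4 adjusted over the list alone), with UQCRC1 at -0.28 and NDUFV1 at -0.19 (camera adjusted p 0.0850). It was called without sgKCNQ3 replicate 2 (0.0255), with limma-voom (0.0463) and by fry (0.0496). Of 25 PI3K-AKT-mTOR components, 11 were higher, including RICTOR (0.33) and IRS1 (0.27), and 3 lower, including SGK1 (-0.30), with 15 adjusted over the list alone (camera adjusted p 0.0850). That list was called without sgKCNQ3 replicate 2 (0.0498), on TPM (0.0303) and by fry (0.00887). Of 24 YAP/TEAD targets, 6 were higher and 9 lower, with ANKRD1 (-0.54) and CCN2 (-0.30) lower, and 16 were called adjusted over the list alone (camera adjusted p 0.199). With the length and GC trends removed the YAP/TEAD list was called lower (median -0.08, adjusted p 5.69e-04, adjusted p = 0.396 with an estimated correlation). Of 21 TGF-beta targets, 4 were higher, including ID2 (0.41) and SMAD6 (0.33), and 9 lower, including COL4A1 (-0.18), with 13 adjusted over the list alone (camera adjusted p 0.415). Of 12 Wnt/beta-catenin targets, 4 were higher, including RNF43 (1.34) and BMP4 (0.58), and 2 lower, including DKK1, with 6 adjusted over the list alone (camera adjusted p 0.638). RNF43 was weakly expressed, at 0.833 CPM in NC and 2.12 CPM in sgKCNQ3.

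Lists of lipid synthesis genes, other potassium channels, replication-dependent histones and neighbours of KCNQ3 were not called by camera. Of 14 fatty acid synthesis genes, 5 were higher, including SCD (0.37) and FASN (0.19), and 2 lower, including ELOVL1 (-0.26), with 7 adjusted over the list alone (camera adjusted p 0.199). Of 23 cholesterol synthesis genes, 4 were higher and 5 lower, including DHCR7 (-0.30) and MVD (-0.36), with 9 adjusted over the list alone (camera adjusted p 0.515). Of 16 other potassium channel genes, 1 was called higher and 1, KCNG1 (-0.15), lower, and 1 was called adjusted over the list alone (camera adjusted p 0.303). Of 30 replication-dependent histone genes listed, only 8 passed the filter in these poly(A)-enriched libraries, at a median of 3.02 CPM in NC. Of these 8, H1-2 (-0.65) was lower, and 1 was called adjusted over the list alone (camera adjusted p 0.340). Of 8 tested neighbours of KCNQ3 in 8q24, EFR3A (0.33) and ASAP1 (0.21) were among 3 higher genes, and NDRG1 (-0.26) and ST3GAL1 (-0.13) were lower, with 5 adjusted over the list alone (camera adjusted p 0.816). No mitochondrially encoded gene was tested. In all, camera with a preset correlation called 12 of 37 lists, 4 higher and 8 lower. Some of the lists called lower share members, such as ATF3, SESN2 and CXCL8, so these calls are not independent results. With an estimated correlation camera called 0 lists at the adjusted threshold (smallest adjusted p 0.199) and 8 at an unadjusted p under 0.05, and fry called 24. For NF-kB targets the estimated correlation (-0.039) lay below the preset 0.01, and the camera adjusted p still rose from 0.00173 to 0.199. In the copy number test described below, camera with an estimated correlation recovered 0 of 29 shifted windows. A call missing with an estimated correlation therefore cannot by itself show that correlation between genes made the preset call. For the heat shock, ribosomal protein and glycolysis lists, however, the estimated correlations were 0.258, 0.175 and 0.113. These lie well above the preset, so correlation between genes may have made those calls. Estimates for the other called lists ran from -0.047 to 0.064. Of the lists that camera did not call, and besides those named with it above, fry called cell cycle inhibitors (adjusted p 0.00205), YAP/TEAD targets (0.00351), fatty acid synthesis genes (0.00887), interferon-stimulated genes (0.0326), unfolded protein response chaperones (0.0496) and other potassium channels (0.0496). On TPM, camera also called replication-dependent histone genes (0.0330).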

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

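The removal of length and GC trends was chosen after the data were seen, and the other alternatives before. DESeq2 called 2322 genes, 1111 higher and 1211 lower, and 29 with a log2 fold change of at least 1 in size (12 higher, 17 lower). On log2(TPM + 1), 2570 genes were higher and 603 lower, and 4 reached that size (1 higher, 3 lower). FPKM sums were lower in sgKCNQ3, so scaling to the same TPM total raised its values relative to FPKM. The median log2 fold change over the tested genes was 0.065 on this scale, against -0.007 with TMM factors. Adding 1 also shrinks the change of weakly expressed genes, and how much each contributed was not tested. KCNQ3 differed by -0.15 on log2(TPM + 1) (adjusted p 0.140, range over alternatives 1.69e-04 to 0.140) and kept its call in the other 15. The number of large changes followed the filter, since weakly expressed genes hold most of them: 94 with no filter (55 higher), and 18 with at least 2 CPM in 3 libraries (9 higher, 9 lower). Leaving out 1 library gave 2687 to 3471 called genes, 1287 to 1710 higher and 1343 to 1761 lower, 63 to 69 large changes (32 to 43 higher, 24 to 32 lower), a KCNQ3 fold of -0.38 to -0.27, an ERK1/2 target median of -0.19 to -0.15 and 9 to 14 called lists. ERK1/2 targets passed with limma-voom (median -0.18), on TPM (-0.074) and by fry (-0.18), and the cause was not tested. Lists called numbered 0 with an estimated correlation and 24 by fry. The ribosomal protein list had a median of -0.049 and turned to higher by camera after the length and GC trends were removed (adjusted p 0.709), with no call in that direction.

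The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.0136, -0.0977 and 0.00776, no pair highest with its own number, and the replicate block gave 3136 called genes and 12 called lists. Over all alternatives, 2327 of 2413 values of the other named genes kept their direction and side of the threshold, 85 lost the call, 1 gained it and 0 reversed. For gene lists, 616 of 666 were the same, 23 lost the call, 26 gained it and 1 reversed. Small changes can be missed at this depth and number of libraries: the simulation recovered 27 of 50 genes at a log2 fold of 0.25. It changed only 200 of 12505 genes, while 29.1% of tested genes were called in the data. The adjusted threshold therefore met a smaller p in the simulation, and the share missed in the data may be lower.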

Other observations

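Several gene groups outside the fixed lists also moved, and they were chosen after their values were seen. Of 6 tested EGF-family ligand genes, 4 were lower in sgKCNQ3: HBEGF fell from 162 ± 8.58 to 108 ± 3.02 CPM (log2 fold change -0.58, edgeR adjusted p 4.55e-10), NRG1 had a log2 fold change of -0.42, AREG -0.31 and TGFA -0.14. Of 3 tested EGF receptor family genes, ERBB3 (1.06) and ERBB2 (0.19) were higher, while EGFR had a value of -0.04 (adjusted p 0.350). Of 5 genes for ligands of immune checkpoint and related receptors, 3 were lower, with CD274, which encodes PD-L1, falling from 126 ± 3.15 to 85.3 ± 1.94 CPM (log2 fold change -0.56), PVR at -0.31 and PDCD1LG2 at -0.86. Of 8 liver and foregut transcription factor genes, 4 were higher, including PROX1 (1.12), ONECUT2 (0.71) and FOXA1 (0.48), and FOXA3 (-0.25, adjusted p 0.0650) and HNF4A (0.15, adjusted p 0.0836) passed no threshold.

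The tests of copy number with a preset correlation and with window medians removed, of the integrated stress response and immediate early lists taken singly, of heat shock genes and of ERK1/2 output were chosen only after the results they bear on had been seen. The removal of length and GC trends was itself added after the data were seen, and the bounds of its tests over called genes, over called stress members and over ribosomal, glycolysis and oxidative phosphorylation genes were written before those results.

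The first pattern is the number of called genes. The real grouping called 3658 genes, 1 of 10 splits of the libraries gave as many, and the highest other split called 1, but 10 splits are too few for a share under 0.05. With each library's length and GC trends removed, 3326 genes were called. Only 2541 of these had been called in the same direction before, so the total does not count calls that stayed. Of 3648 genes called before, those 2541 (69.7%, 95% score interval 68.1 to 71.1) stayed called in the same direction. The other 1107 did not and may owe their call to the trends. The share that stayed argues against the trends, as fitted, as the whole cause of the calls. Trends that the splines missed stay open. With window medians removed, 2742 of 3621 called genes (75.7%, 74.3 to 77.1) stayed called in the same direction. That argues against copy number differences over 10 Mb windows as the whole cause, while a part of the calls and shorter segments stay open. Median log2 fold changes of windows with 20 genes or more ran from -0.13 to 0.15. Both shares are over genes picked for being called in these libraries. Both intervals take genes as independent, which they are not, and so are too narrow. The copy number test set beforehand found 0% of called genes in 10 Mb windows that moved together with an estimated correlation, but it was set aside as it recovered 0 of 29 windows shifted by 0.32, whereas the preset correlation recovered 29 and put 13.6% of called genes in 22 called windows of 287.

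The second pattern is the fall of stress and immediate early genes. The test set beforehand gave a median of -0.25 (95% bootstrap interval -0.31 to -0.15) over 33 called members after removal of the length and GC trends, its upper end just past the bound of -0.15, and it was set aside because its genes were picked for being called. Over all 23 members, the integrated stress response median went from -0.21 to -0.15 (-0.36 to -0.11) with the list still called at the preset correlation (adjusted p 8.74e-04, adjusted p = 0.399 with an estimated correlation), and that median argues against these trends as its whole cause. Immediate early genes went from -0.18 to -0.15 (-0.25 to -0.03) and lost their list call (adjusted p 0.323) as the mean shrank from -0.15 to -0.11 with 13 members called lower and 3 higher after removal, so the trends may account for part of that list. Harvest stress in the NC cultures and lower ERK1/2 output in sgKCNQ3 both stay open: the heat shock median was 0.15 (-0.02 to 0.34), and the ERK1/2 target list had p = 0.216 with an estimated correlation, with 10 members lower and 5 higher.

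The third pattern is the slightly negative median of ribosomal protein, glycolysis and oxidative phosphorylation genes, of which the last were not called as a list. Over their 98 members the median went from -0.068 to -0.044 (95% bootstrap interval -0.060 to -0.029) when the length and GC trends were removed. Taken singly, it went from -0.074 to -0.049 for ribosomal protein genes and from -0.093 to -0.027 for glycolysis genes. The oxidative phosphorylation median stayed at -0.044. The pooled value lies past the bound of -0.04 written beforehand, but its interval crosses that bound. A trend over transcript length therefore cannot be told apart from a change in these genes. It may account for part of the pooled value, though the oxidative phosphorylation median did not move. No biological explanation of this pattern was tested.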
